A study of Rattus norvegicus with 30 samples.

How the data were processed

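The series holds 30 rat samples: 6 single-cell libraries, analysed here, and 24 spatial libraries, not analysed here. The single-cell libraries were made with a droplet-based protocol, 1 library per group. The macrophage set had the groups IFNg-LPS (the control), IL-4 and pZCO-MSCs-DS. The joint set had the groups Control, HA-MSCs-DS and pZCO-MSCs-DS, with knee cartilage as the labelled tissue. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR were used in the study, with no role given for each. The genome build is not given in the sources used here. The deposited matrices hold the count of each gene in each cell, in whole numbers, and per the file headers they were written by PISA 0.12 (macrophage set) and 1.0 (joint set). The headers do not say whether reads were collapsed by molecular identifier. The counts were taken as UMIs, as usual for this kind of library, and the intervals would be too narrow if they were reads.

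The files list 18295, 18257 and 18346 genes for the IFNg-LPS, IL-4 and pZCO-MSCs-DS macrophages and 20923, 20549 and 20857 for the Control, HA-MSCs-DS and pZCO-MSCs-DS joints. Every listed gene had at least 1 count, so a gene missing from 1 list was set to 0 there. Barcodes had at least 1000 counts each, so cells had been selected before deposition. Barcodes with at least 300 detected genes and at most 20% of counts from mitochondrial genes were kept, which removed 0, 0 and 14 barcodes of the macrophage set and 44, 62 and 94 of the joint set. Doublets were kept. Scrublet, run per library, called none in IFNg-LPS, IL-4, Control and pZCO-MSCs-DS joint cells, and 529 (3.55%) cells of the pZCO-MSCs-DS macrophages and 362 (3.42%) of the HA-MSCs-DS joint. For libraries of this size a count of 0 is unlikely to mean that they held no doublets, and why none were called was not tested. The macrophage and joint sets were annotated on different gene lists and are not compared with each other. In the joint files some ribosomal genes (Rpl41, Rps26, Rps18) are not listed while genes that neighbour or overlap them in position have high counts, so single genes of that kind were not named.

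The macrophage libraries and the joint libraries were clustered separately with no batch integration: log-normalized counts, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1. Clusters were named from 23 fixed marker lists. A marker counted as detected in a cluster at 50 CPM or more, in at least 10% of cells and at 2 or more times the median cluster. A cluster took the class with the largest share of its measured markers detected, from at least 3. It stayed unnamed with fewer, when more markers of another class were among its leading genes, or when it was shallow without such markers. This gave names to 20 of 27 macrophage-set clusters and 28 of 31 joint clusters. The rule was revised after clusters had been seen, and the earlier versions, which ranked classes by the number of markers, named 19 and 18 of the first and 24 and 27 of the second and are among the alternatives. Classes are called "-like" since only transcripts define them. Class comparisons needed 50 cells in each library.

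Counts were summed over the cells compared and given as CPM, with exact Poisson 95% intervals, and the ratio of 2 libraries with the exact conditional binomial interval. Shares of cells have exact Clopper-Pearson 95% intervals. All cover counting error only, since cells are not replicates. With 1 library per group no test across samples was run, and no number of changed genes is given. The 23 gene lists, 6 pairs of libraries, filters, pseudocount (1 CPM), size limits and the rule for named genes were chosen before the data were examined. Per that rule, the genes named in a pair are the 8 with the highest and the 8 with the lowest log2 ratio of (CPM + 1) among genes with 50 CPM or more in either library, leaving out mitochondrial genes and placeholder names, the 2 members furthest apart and the most abundant member of each list, and a fixed set: Nos2, Tnf, Il1b, Il6, Cxcl10, Arg1, Mrc1, Cd163, Il10, Ccl22 and Ptgs2 in macrophages, and Col2a1, Acan, Prg4, Sox9, Col10a1, Mmp3, Mmp13, Adamts5, Col1a1, Il6, Il1b and Tnf in joints. The text prints part of them. A list member was measured at 5 CPM or more in either library. It counted as higher or lower at a ratio of (CPM + 1) of at least 1.5 whose interval left out 1. The interval of a list median came from 2000 Poisson resamples, and its percentile from 10000 random lists matched on expression in 20 bins. A percentile describes these libraries and is not a test. Lists covered inflammation, interferon, class II, IL-4 response, efferocytosis, glycolysis, the respiratory chain, oxidative, metal, hypoxia and endoplasmic reticulum stress, glucocorticoid response, eicosanoids, the cell cycle, immediate early genes, apoptosis, cartilage matrix, hypertrophy, matrix-degrading enzymes, protease inhibitors, fibrillar matrix, trophic factors and mesenchymal surface genes.

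Free RNA can put counts of one class's genes into cells of another. In each library and class, the free-RNA share was estimated from markers of other classes, and a gene stood above free RNA in a class at 3 or more times the predicted level and 5 CPM or more in either library. Genes named within a class stood above it unless the text says otherwise or gives a share of cells as a background. The estimate is a median over markers, and some transcripts, such as Col2a1 in the joints, lie above it in several classes. GFP-rich stromal-like cells are stromal-like clusters with GFP at 5 or more times the library's median cluster. Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs (macrophage set) or 1500 (joint set), leaving out shallower cells, and shares before thinning are named as such. The free-RNA and GFP limits, the split by class, the choice of which class-level medians to report and the definition of a called value were made after the data had been seen.

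The alternatives were no cell filter, a stricter filter (1000 genes, 10% mitochondrial counts), doublets left out, trimmed-mean (TMM) scaling from edgeR, a pseudocount of 0.1, list members with any count, means over cells of counts per 10000, macrophage-like clusters only, and Leiden resolutions of 0.5 and 1.5. Added after the data were seen were other naming rules, clusters 18 and 21 counted as macrophage-like, the unnamed cluster 0 of the macrophage set counted as stromal-like, its cluster 26 not counted as macrophage-like, members above free RNA, TMM scaling or doublets left out within classes, GFP-rich cells chosen by GFP UMIs (5 or more, at 1000 CPM or more), and the planned settings for the lists not named in the plan. The intervals and calls were tested on simulated data at each pair's depth with 200 changed genes: intervals held the true ratio for 94.9% to 95.6% of genes, 0 unchanged genes were called, and 98.8% to 100% of genes changed 2-fold and 10.9% to 39.4% of those changed 1.5-fold were called. Both simulated libraries were Poisson counts from a shared profile, with no variation between cells or libraries. Such coverage follows from that setting and says nothing of false calls between real libraries. A simulated list of unchanged genes lay at percentiles from 4.5 to 98.5 in the pairs. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.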

Results

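Single-cell RNA sequencing gave 6 rat libraries, 1 per group, in a set of 3 macrophage cultures and a set of 3 joint samples. In the macrophage set, cultures driven to a pro-inflammatory state with interferon-γ and lipopolysaccharide were the control (IFNg-LPS). In the other 2 groups such macrophages were cultured with interleukin-4 (IL-4) or pZCO-MSCs-DS, a system of coacervate, cells and drug. In the joint set, with knee cartilage as the labelled source, Control was compared with osteoarthritic joints injected with hyaluronic acid, cells and drug (HA-MSCs-DS) or with the coacervate system (pZCO-MSCs-DS). The injected cells carried green fluorescent protein (GFP), and the GFP-positive cells of the injected joints were sorted before sequencing. What the Control library was sorted for, and whether its joints were osteoarthritic, is not in the labels.

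The IFNg-LPS, IL-4 and pZCO-MSCs-DS macrophage libraries held 176598903, 344825980 and 290365277 counts, with 12454, 17497 and 14905 cells kept and a median of 4607, 14219 and 12092 unique molecular identifiers (UMIs) per cell. The Control, HA-MSCs-DS and pZCO-MSCs-DS joint libraries held 64222210, 123054481 and 84781977 counts in 9431, 10593 and 6293 kept cells, with a median of 4086, 7164 and 4866 UMIs. With 1 library per group no difference has a replicate check and no test across samples was possible. Values therefore describe these libraries, and all intervals are 95% intervals of counting error only. Expression is given as CPM, the counts of a gene in a total scaled to 1e6, over the summed counts of the cells named. Log2 ratios are of CPM + 1, and a list member was called higher or lower at a ratio of at least 1.5 whose counting interval left out 1. A list's percentile is the place of its median among 10000 random lists of the same size and expression.

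To see which cells the cultures held, the 3 macrophage libraries were clustered together and the clusters were named from fixed markers. Macrophage-like cells made up 80.4% [79.7, 81.1] of the IFNg-LPS cells, 37.4% [36.7, 38.1] of the IL-4 cells and 57.0% [56.2, 57.8] of the pZCO-MSCs-DS cells. Stromal-like cells, rich in Col1a1, Col1a2 and other fibroblast markers, made up 8.04% [7.57, 8.53], 34.8% [34.1, 35.5] and 40.1% [39.4, 40.9] in that order. They were far larger in RNA content, at a median of 55061, 32926 and 33398 UMIs against 3685, 10365 and 7922 in macrophage-like cells, and so gave 31.4%, 60.6% and 72.0% of all counts. Unnamed clusters held 9.53%, 27.7% and 2.69% of the cells. Most of those in the IL-4 library lay in clusters 18 and 21, which came closest to macrophages and would bring its macrophage-like share to 62.8%. Most of those in the IFNg-LPS library lay in cluster 0 (1130 cells), which had 6 stromal markers but Acan among its leading genes. It would bring the stromal-like share of that library to 17.1% and the share of its counts to 65.0%. Nearly every cluster of this set came from a single library, and the shares moved with the grain of the clustering. With fewer, broader clusters (Leiden resolution 0.5) the macrophage-like share of the IL-4 library was 8.39%. With finer ones (1.5) that of the IFNg-LPS library was 46.2%. Of the 10010 macrophage-like cells of that library, 4229 lay in cluster 5, a shallow cluster with a median of 2015 UMIs. It was named from 3 macrophage markers, the fewest allowed, and Col1a1 was detected in it as well. Whether its cells were those that lost the name at the finer resolution was not tested.

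**Figure D1:**
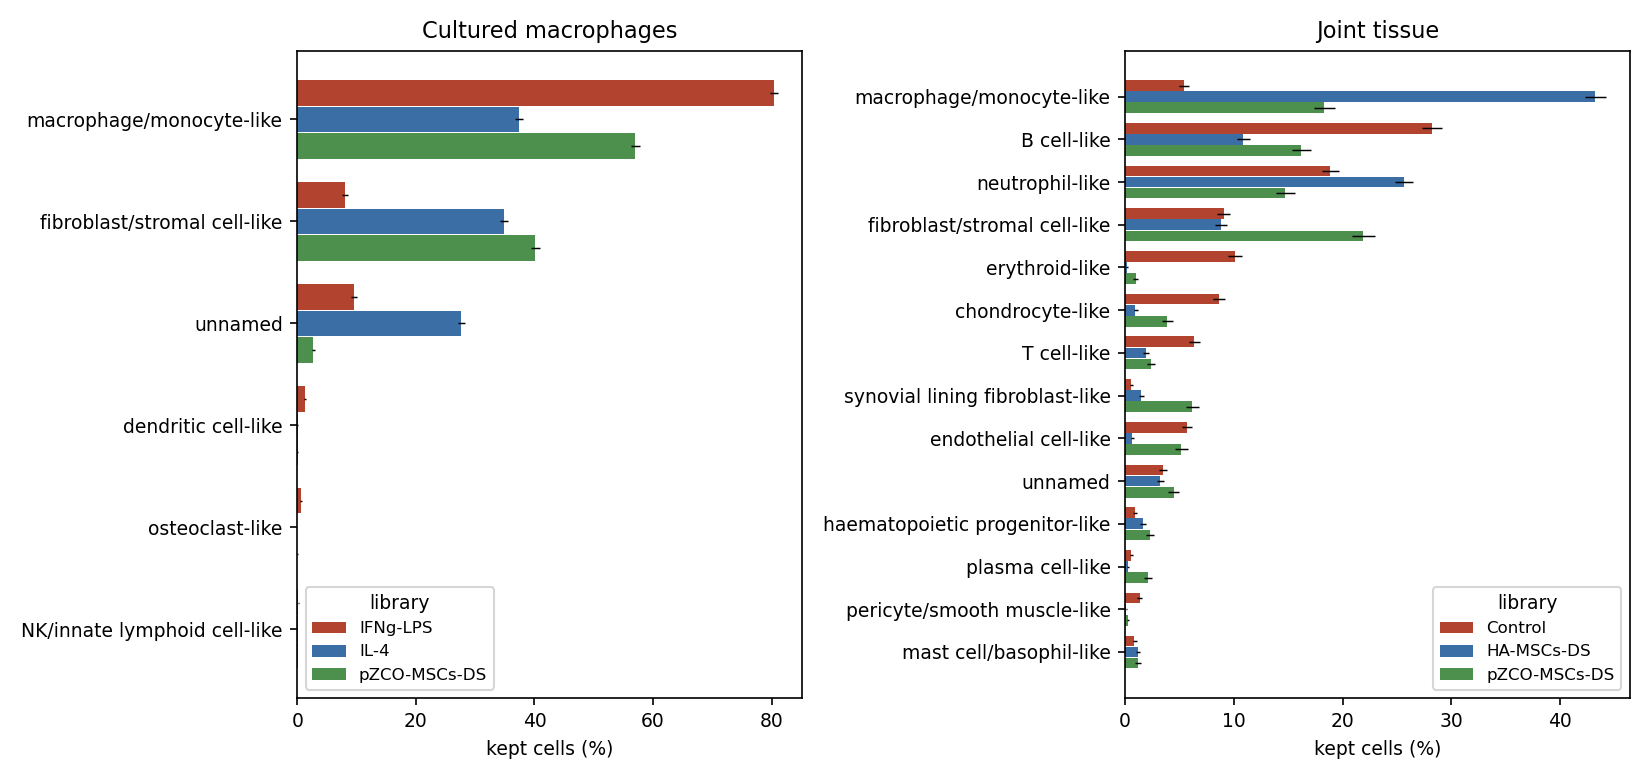
Share of kept cells (percent) in each class of cells, for the 3 macrophage cultures and the 3 joint libraries; bars are single libraries and error bars are exact 95% binomial intervals. Macrophage-like cells are the largest class in the IFNg-LPS (80.4%), IL-4 (37.4%) and pZCO-MSCs-DS (57.0%) cultures and in the HA-MSCs-DS joint (43.3%).

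To ask how the coacervate system altered pro-inflammatory macrophages, the pZCO-MSCs-DS culture was compared with the IFNg-LPS culture over all kept cells. The T cell-attracting chemokine gene Cxcl10 stood at 29.2 against 5066 CPM, 170.1 to 178 times lower, and Nos2, which encodes inducible nitric oxide synthase, at 9.86 against 1766 CPM, 173 to 186 times lower. Some genes of alternative activation stood far higher: the lectin gene Clec10a at 237 against 0.872 CPM, 232 to 320.5 times higher. The arginase gene Arg1 was at 1096 against 51.9 CPM, and the mannose receptor gene Mrc1 at 243 against 11.1 CPM. Arg1 was not particular to macrophages: it stood at 1181 against 45.9 CPM in stromal-like cells and at 877 against 109.8 CPM in macrophage-like cells. Not every inflammatory gene was lower. Il1b was at 153 against 687 CPM, but the monocyte-attracting chemokine gene Ccl2 (10204 against 8010.0 CPM), Il6 (90.8 against 62.7 CPM) and the cyclooxygenase gene Ptgs2 (226 against 179 CPM) stood slightly above the control. Within stromal-like cells Il6 and Ptgs2 did so too (116 against 91.0 CPM and 299 against 281 CPM), while in macrophage-like cells Il6 (26.8 against 87.3 CPM) and Ptgs2 (37.5 against 75.2 CPM, not above free RNA) were lower. The stromal-like cells of these cultures may differ in source, since the labels name added cells for pZCO-MSCs-DS alone.

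Of the interferon response list, 0 of 38 measured members were higher and 37 were lower in the macrophage cultures given pZCO-MSCs-DS (median log2 ratio -3.60 [-3.63, -3.58], percentile 0). They included the antiviral genes Rsad2 (4.47 against 967 CPM), Cmpk2 (2.05 against 452 CPM), Mx2 (12.1 against 1390.3 CPM) and Ifit3 (41.0 against 1870.4 CPM). Of the pro-inflammatory mediators, 2 of 33 were higher and 24 lower (median -1.74 [-1.75, -1.69], percentile 0), among them Acod1, the itaconate-making enzyme (9.07 against 712 CPM). Tnf was low in both libraries, at 1.97 against 6.01 CPM. Of the list of IL-4 response and alternative activation, 16 of 30 were higher and 5 lower (median 0.61 [0.54, 0.67], percentile 100). Il10 (0.696 against 19 CPM) and Ccl22 (41.4 against 83.9 CPM) went the other way, though Ccl22 stood at 112 against 102 CPM in macrophage-like cells with cluster 26 counted in. Matrix genes and protease inhibitors were higher, and the stromal-like share of the counts rose with them, from 31.4% (65.0% with cluster 0 counted in) to 72.0%. Higher were 17 of 25 genes of fibrillar and fibrous matrix, and 0 lower (median 1.23, percentile 100, and 0.62 within stromal-like cells), with the matricellular gene Ccn2 (3602 against 183 CPM) and Postn (268 against 26 CPM). Protease inhibitors had 7 of 13 higher, 2 lower (median 0.75, percentile 100), among them Timp1 (7669.6 against 3695 CPM). Trophic and repair factors were mixed, with 10 higher and 8 lower of 23 (median 0.49, percentile 99.7), and the anti-inflammatory factor Tnfaip6 at 638 against 19.9 CPM. That median changed sign with members under 5 CPM counted in.

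Glycolysis, hypoxia and oxidative stress genes leaned lower in this pair of macrophage cultures. Glycolysis had 9 of 19 lower (median -0.49, percentile 0.355), led by the regulator Pfkfb3 (21.3 against 126 CPM), and the hypoxia response 1 of 17 higher, 9 lower (median -0.59, percentile 0.0600), led by Adm (8.61 against 95.7 CPM). The oxidative stress response had 3 of 17 higher, 10 lower (median -0.82, percentile 0), with Nqo1 lower (307 against 1044 CPM) and the iron-storage gene Fth1 higher (58658 against 32356 CPM). The cell cycle list had 13 of 26 lower (median -0.62, percentile 0) and apoptosis 2 of 20 higher, 7 lower (median -0.37, percentile 0.0700). The respiratory chain (4 of 31 higher, median 0.25), class II antigen presentation (1 of 9 higher, 2 lower, median -0.24) and efferocytosis and lipid handling (7 of 23 higher, 8 lower, median -0.08) had medians closer to 0. So had the metal response (1 of 5 higher, median 0.23) and endoplasmic reticulum stress (2 of 18 higher, 1 lower, median 0.12). The same held for the glucocorticoid response (2 of 11 higher, 2 lower, median -0.03), eicosanoid synthesis (3 of 10 higher, 3 lower, median 0.25) and immediate early and heat shock genes (2 of 19 higher, 6 lower, median -0.34). Mesenchymal surface genes (6 of 16 higher, 3 lower, median 0.32) leaned slightly higher. Matrix-degrading enzymes (8 of 21 higher, 3 lower, median 0.13) gave -0.05 with every member counted in and -0.35 within stromal-like cells. Few skeletal genes were measured: cartilage matrix had 2 of 8 higher, 5 lower (median -1.46) and hypertrophy and mineralization 1 of 9 higher, 4 lower (median -0.57).

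Within macrophage-like cells alone, clusters 23 to 26 of the pZCO-MSCs-DS culture were set against clusters 2, 4 and 5 of the IFNg-LPS culture, which hold most of the class in each. The chemokine gene Ccl17 stood at 1275 against 21.9 CPM, Mrc1 at 754 against 31.6 CPM, Arg1 at 877 against 109.8 CPM, the cathepsin gene Ctsc at 1442 against 61.2 CPM and Ctsl at 2547 against 373 CPM. Nos2 stood at 29.2 against 4392 CPM, the receptor gene Slamf7 at 4.38 against 730.3 CPM and the interleukin-1 antagonist gene Il1rn at 125 against 3235 CPM. Cluster 26 (419 cells) had Ccl17 and Ccl22 among its leading genes, and Ccl22 led in the dendritic cell-like cluster as well. Without it the log2 ratio of Ccl17 was 5.03 against 5.80 with it, that of Ccl22 -1.60 against 0.13, and the IL-4 response median 0.31. Pro-inflammatory mediators had 4 of 33 higher, 28 lower (median -1.64 [-1.68, -1.60]) and the interferon response 1 of 39 higher, 38 lower (median -3.05 [-3.10, -2.99]). The IL-4 response list had 14 of 31 higher, 6 lower (median 0.30 [0.28, 0.32], below the value over all cells). The respiratory chain had 16 of 31 higher (median 0.65) and glycolysis 11 of 19 lower (median -0.81). The hypoxia response had 1 of 16 higher, 14 lower (median -1.37) and the oxidative stress response 3 of 17 higher, 10 lower (median -0.72). The metal-binding genes Mt1 (920.0 against 238 CPM) and Mt2A (396 against 186 CPM) were higher, and the metal response had 3 of 5 higher, 1 lower (median 0.61). Class II (1 of 9 higher, 1 lower, median 0.07), apoptosis (4 of 20 higher, 8 lower, median -0.15) and the cell cycle (3 of 13 higher, 5 lower, median -0.54) lay near 0 or were mixed. In stromal-like cells, clusters 10, 12 and 14 against cluster 1 without the unnamed cluster 0, the interferon response (38 of 38 lower, median -3.90) and pro-inflammatory mediators (5 of 30 higher, 19 lower, median -1.22) were lower too. Fibrillar matrix was higher there (14 of 25 higher, median 0.62), with Tnfaip6 at 851 against 43.2 CPM and Ccn2 at 4825 against 373 CPM. The hypoxia response (2 of 17 higher, 6 lower, median -0.22), the cell cycle (9 of 26 lower, median -0.29) and matrix-degrading enzymes (2 of 23 higher, 9 lower, median -0.35) lay closer to 0. With cluster 0 counted in, the medians of these 6 lists were -3.94, -0.97, 1.13, -0.24, -0.53 and 0.40, so that of the enzymes turned. The labels name added cells for pZCO-MSCs-DS alone, and what part of its stromal-like cells was added is not known. The stromal-like cells compared may therefore differ in source and exposure, and the ratios need not be changes within the same cells.

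To set a known anti-inflammatory signal beside the coacervate system, the IL-4 culture was compared with the IFNg-LPS culture. Inflammatory and interferon genes were lower with IL-4, some of them close to absent: Nos2 stood at 0.0174 against 1766 CPM, and the chemokine genes Cxcl11 at 0.539 against 4192 CPM and Cxcl9 at 0.0203 against 414 CPM. Ccl5 was at 6.53 against 3081 CPM, 452 to 492 times lower, and Il1b at 25.3 against 687 CPM, 26.6 to 27.7 times lower. Some lectin genes of alternatively activated macrophages were higher, with Clec10a at 307 against 0.872 CPM, Clec4a3 at 343 against 3.32 CPM and Mrc1 at 478 against 11.1 CPM, 41.1 to 44.9 times higher. Cd163, the haemoglobin scavenger receptor gene, was detected at 8.92 against 0.0340 CPM. Arg1 stood at 332 against 51.9 CPM, with a smaller difference in macrophage-like cells (167 against 109.8 CPM) than in stromal-like ones (406 against 45.9 CPM). Dividing-cell genes were higher as well, such as Ube2c (122 against 16.6 CPM) and Cdc20 (55.8 against 8.15 CPM).

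Of the interferon response, 0 of 38 measured members were higher and 38 lower in the IL-4 macrophage culture (median -4.53 [-4.57, -4.49], percentile 0). Of the pro-inflammatory mediators 0 of 33 were higher and 32 lower (median -3.18 [-3.24, -3.12], percentile 0). Il6 (6.02 against 62.7 CPM), Ptgs2 (32.3 against 179 CPM) and Ccl2 (2679.8 against 8010.0 CPM) were all lower. The IL-4 response list had 17 of 31 higher, 8 lower (median 0.76 [0.74, 0.81], percentile 100) and the cell cycle 28 of 31 higher (median 1.42 [1.37, 1.49], percentile 100). Lower together were the hypoxia response (16 of 17 lower, median -1.85), the oxidative stress response (15 of 17 lower, median -1.37) with the haem-degrading gene Hmox1 (169.9 against 1974 CPM), and apoptosis (15 of 19 lower, median -1.26). So were glycolysis (17 of 19 lower, median -1.11) with the glucose transporter gene Slc2a1 (71.3 against 529 CPM), and the metal response leaned that way (1 of 5 higher, 3 lower, median -0.81). Higher were fibrillar matrix (14 of 25 higher, 2 lower, median 0.80) and the respiratory chain (17 of 31 higher, median 0.59) with Atp5f1b (865 against 391 CPM). Mesenchymal surface genes leaned higher (8 of 16 higher, 4 lower, median 0.45). Efferocytosis and lipid handling (9 of 23 higher, 6 lower, median 0.39) was mixed, with the complement gene C1qb at 305 against 40.6 CPM. Glucocorticoid response (2 of 12 higher, 6 lower, median -0.36), trophic factors (8 of 22 higher, 10 lower, median -0.07) and eicosanoid synthesis (5 of 11 higher, 4 lower, median 0.18) were mixed too. With means over cells of counts per 10000, the efferocytosis, trophic and eicosanoid medians turned to -0.07, 0.67 and -0.09. Class II (2 of 9 higher, median 0.06) and protease inhibitors (4 of 13 higher, 6 lower, median 0.02) had medians near 0, as had endoplasmic reticulum stress (6 of 18 higher, 4 lower, median 0.19) and immediate early genes (3 of 20 higher, 4 lower, median 0.01).

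In macrophage-like cells, mostly clusters 19, 20 and 22 of the IL-4 culture against clusters 2, 4 and 5, the pattern was the same in sign and mostly larger. The cell cycle had 31 of 31 higher (median 3.13 [3.04, 3.23]), with Mki67 at 102 against 1.97 CPM, and the respiratory chain 24 of 31 higher (median 1.14). All 678 cells of cluster 22, led by Mki67, Ube2c and Top2a, were among the 6541 IL-4 cells of this class. With clusters 18 and 21 counted in the class would hold 10996 cells, so cluster 22 weighs more here than it would then. Pro-inflammatory mediators had 33 of 33 lower (median -3.45) and the interferon response 37 of 38 lower (median -4.33). The IL-4 response list had 18 of 32 higher, 10 lower (median 0.93), with the transcription factor gene Irf4 at 60.5 against 0.429 CPM, against Il1rn at 11.8 against 3235 CPM. Glycolysis (15 of 19 lower, median -1.19), hypoxia (14 of 16 lower, median -2.10) and oxidative stress (1 of 17 higher, 16 lower, median -1.96) were lower, and so were apoptosis (1 of 20 higher, 15 lower, median -1.55) and the metal response (1 of 5 higher, 3 lower, median -1.65). Class II leaned slightly higher (3 of 9 higher, median 0.37). In stromal-like cells, clusters 9 and 16 against cluster 1, interferon (38 of 38 lower, median -4.61), pro-inflammatory (29 of 29 lower, median -3.15), hypoxia (16 of 17 lower, median -1.77) and matrix-degrading genes (4 of 24 higher, 11 lower, median -0.47) were lower. Cell cycle (30 of 31 higher, median 1.67) and fibrillar matrix genes (15 of 26 higher, 2 lower, median 0.68) were higher. With cluster 0 counted in, the medians of these 6 were -4.69, -2.70, -1.64, 0.14, 1.28 and 0.97, and the enzymes turned here too.

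To tell the coacervate system from IL-4, the pZCO-MSCs-DS culture was compared with the IL-4 culture. The coacervate culture kept more inflammatory transcripts: Cxcl11 stood at 1355 against 0.539 CPM, Ccl5 at 1137 against 6.53 CPM, 167 to 181 times higher, and the neutrophil-attracting chemokine gene Cxcl3 at 1005 against 24.3 CPM, 40.5 to 42.3 times higher. Il1b stood at 153 against 25.3 CPM and Il6 at 90.8 against 6.02 CPM. Higher too were Gdf15 at 205 against 3.06 CPM, the transcription factor gene Ddit3 at 366 against 35.4 CPM, the haem-degrading gene Hmox1 at 707 against 169.9 CPM and the metal-binding gene Mt1 at 427 against 55.5 CPM. Gdf15 and Ddit3 were leading genes of stromal-like cluster 10, with 462 pZCO-MSCs-DS and 0 IL-4 cells. Il6 stood at 116 against 9.33 CPM in stromal-like cells, and at 26.8 against 0.863 CPM in macrophage-like cells, not above free RNA. Stromal-like cells gave 72.0% of the pZCO-MSCs-DS counts and 60.6% of the IL-4 counts, so values over all cells are not those of macrophages alone. Dividing-cell genes were lower, such as Ube2c (9.33 against 122 CPM), as was the growth factor gene Igf1 (35.9 against 417 CPM). Arg1 was higher in the coacervate culture (1096 against 332 CPM) and Mrc1 lower (243 against 478 CPM).

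Pro-inflammatory mediators had 26 of 31 higher, 1 lower (median 1.94 [1.92, 1.99], percentile 100) in this pair of macrophage cultures, and the cell cycle 0 higher and 31 lower of 31 (median -2.25 [-2.32, -2.20], percentile 0). Higher in the coacervate culture were hypoxia (11 of 16 higher, median 1.10) with Ero1a (338 against 67.9 CPM), oxidative stress (13 of 17 higher, median 1.0) and trophic factors (17 of 21 higher, 2 lower, median 1.0) with Tnfaip6 (638 against 48.3 CPM). Glycolysis (10 of 19 higher, 1 lower, median 0.82) and apoptosis genes (10 of 20 higher, median 0.62) were higher, the latter with Pmaip1 (33.8 against 3.47 CPM). So were protease inhibitors (6 of 12 higher, 1 lower, median 0.56) and interferon response genes (16 of 34 higher, 2 lower, median 0.49). The metal response leaned higher (2 of 5 higher, median 0.49), and endoplasmic reticulum stress was split (4 of 18 higher, 3 lower, median -0.22). The respiratory chain (4 of 31 lower, median -0.41) and class II (1 of 9 higher, 3 lower, median -0.36) had medians below 0 but few members called, and efferocytosis genes leaned lower (3 of 23 higher, 9 lower, median -0.33). Among the enzymes that degrade matrix (7 of 21 higher, 3 lower, median 0.26), the stromelysin gene Mmp3 stood at 2489 against 213 CPM. Mmp3 and Tnfaip6 were leading genes of stromal-like cluster 12, with 2345 pZCO-MSCs-DS and 3 IL-4 cells. In macrophage-like cells, clusters 23 to 26 against clusters 19, 20 and 22, pro-inflammatory (27 of 32 higher, 2 lower, median 2.58), interferon (27 of 37 higher, 2 lower, median 0.98) and oxidative stress genes (16 of 17 higher, median 1.61) were higher. So were metal (4 of 5 higher, 1 lower, median 0.83), apoptosis (14 of 20 higher, median 0.95) and hypoxia genes (9 of 14 higher, 1 lower, median 0.83). Cell cycle (31 of 31 lower, median -3.27, with clusters 18 and 21 left out of the IL-4 class) and respiratory chain genes (18 of 31 lower, median -0.66) were lower. There Fth1 stood at 122382 against 14973 CPM and the cell cycle inhibitor gene Cdkn1a at 1054 against 103 CPM. The IL-4 response list was split in the whole cultures (9 of 30 higher, 11 lower, median -0.21) and in macrophage-like cells (16 of 33 higher, 9 lower, median 0.46), where clusters 18 and 21 brought the median to -0.01. Stromal-like cells, clusters 10, 12 and 14 against 9 and 16, gave the same signs for pro-inflammatory (22 of 27 higher, median 1.49), hypoxia (15 of 17 higher, 1 lower, median 1.31) and cell cycle genes (31 of 31 lower, median -2.15). These cells too may differ in source, since added cells are named for pZCO-MSCs-DS alone.

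Per cell, each cell was thinned to 2000 UMIs and shallower cells were left out (2423 of 10010, 458 of 6541 and 730 of 8502 macrophage-like cells of the IFNg-LPS, IL-4 and pZCO-MSCs-DS cultures). Nos2 was then found in 98.9%, 0.0164% and 3.22% of macrophage-like cells (98.1%, 0.0306% and 7.52% before thinning). Stromal-like cells, where Nos2 did not stand above free RNA, gave 46.1%, 0% and 0.463%. Mrc1 was found in 6.06%, 83.7% and 64.3% of thinned macrophage-like cells (12.7%, 97.7% and 84.2% before), against 0.302%, 16.4% and 8.48% of stromal-like cells. Il1b was found in 70.2%, 10.4% and 29.1% (81.2%, 24.1% and 49.5% before), against 15%, 0.987% and 4.23% of stromal-like cells.

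**Figure D2:**
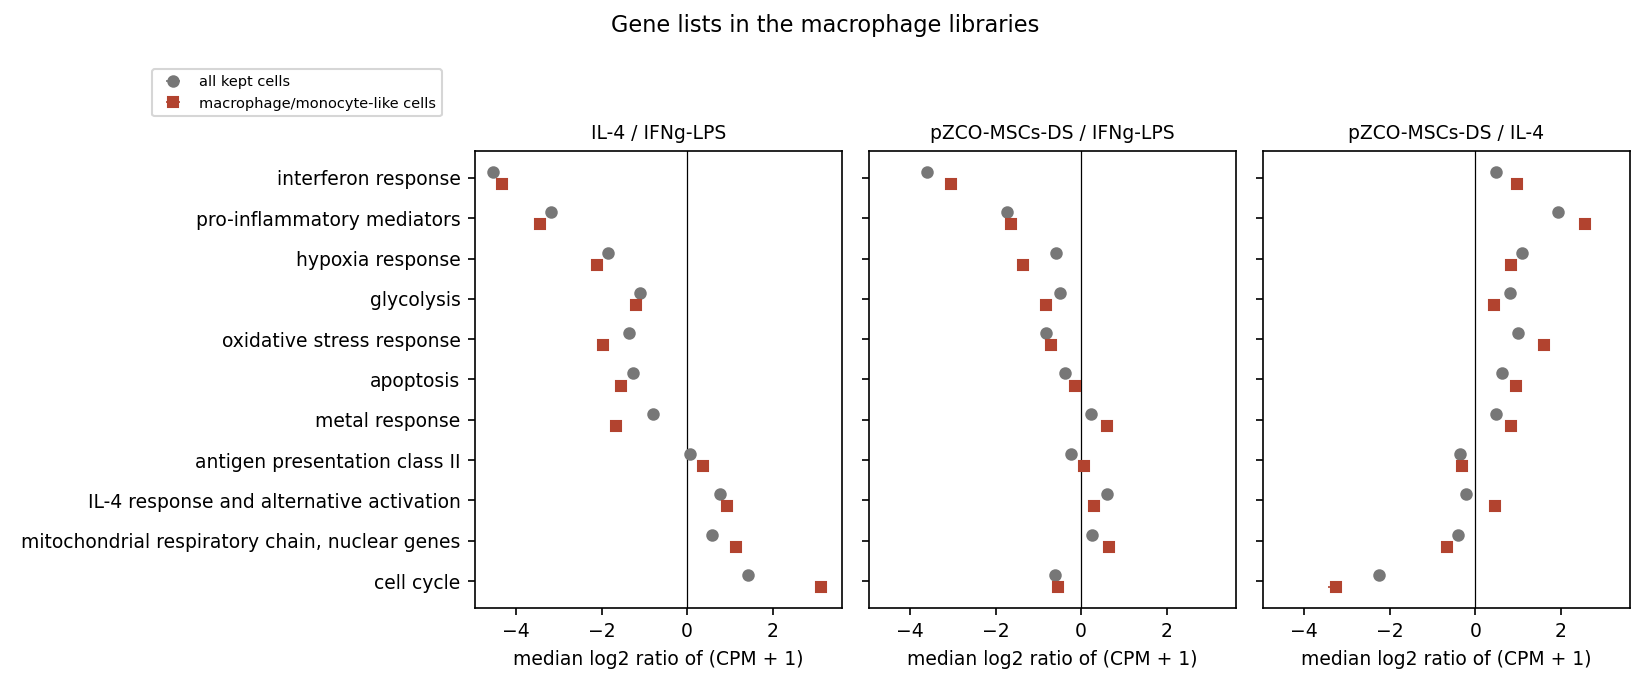
Median log2 ratio of (CPM + 1) for 11 gene lists in the 3 pairs of macrophage libraries; circles are all kept cells, squares are macrophage-like cells, and bars are 95% intervals of counting error. The interferon response has the lowest median against IFNg-LPS in all kept cells, at -3.60 with pZCO-MSCs-DS and -4.53 with IL-4.

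The joint libraries held blood, marrow, joint and stromal classes in different proportions. Macrophage-like cells made up 5.41% [4.96, 5.88] of Control, 43.3% [42.3, 44.2] of HA-MSCs-DS and 18.3% [17.4, 19.3] of pZCO-MSCs-DS cells, and stromal-like cells 9.07% [8.49, 9.66], 8.79% [8.26, 9.34] and 21.9% [20.9, 23.0]. In the same order, neutrophil-like cells made up 18.9%, 25.6% and 14.7%, B cell-like cells 28.2%, 10.8% and 16.2%, T cell-like cells 6.37%, 1.89% and 2.35%, chondrocyte-like cells 8.61%, 0.944% and 3.89% and endothelial-like cells 5.70%, 0.651% and 5.16%. Erythroid-like cells made up 10.1%, 0.132% and 0.953%, and synovial lining fibroblast-like cells 0.583%, 1.46% and 6.18%. A sort sets such shares, so they describe the sorted cells and not the joint. GFP transcripts were concentrated in stromal-like clusters: in cluster 29 of HA-MSCs-DS (720 cells, 1661 CPM, 87.9% of cells with GFP) and cluster 7 of pZCO-MSCs-DS (901 cells, 3276 CPM, 98.9%), against a median cluster of 26.5 and 180.4 CPM. These clusters were deep, at medians of 25771 and 47894 UMIs, which raises such shares. As a background, 36.3% of macrophage-like cluster 19 in HA-MSCs-DS (17925 UMIs) and 67.4% of progenitor-like cluster 26 in pZCO-MSCs-DS (9072.5 UMIs) held GFP. Less GFP, but more than in the median cluster, was in the lining fibroblast-like cluster 10 (115 CPM in HA-MSCs-DS and 466 in pZCO-MSCs-DS) and in the chondrocyte-like cluster 18 of pZCO-MSCs-DS (492 CPM, with 5 or more GFP UMIs in 29.7% of cells). Cluster 18 had a median of 19144 UMIs there, and progenitor-like cluster 26, at 9072.5 UMIs, had 5 or more in 19.4% of cells. All these shares of cells were taken before thinning to a common depth. Clusters 29 and 7, with the 54 pZCO-MSCs-DS cells of cluster 29, are called GFP-rich stromal-like cells here.

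**Figure D3:**
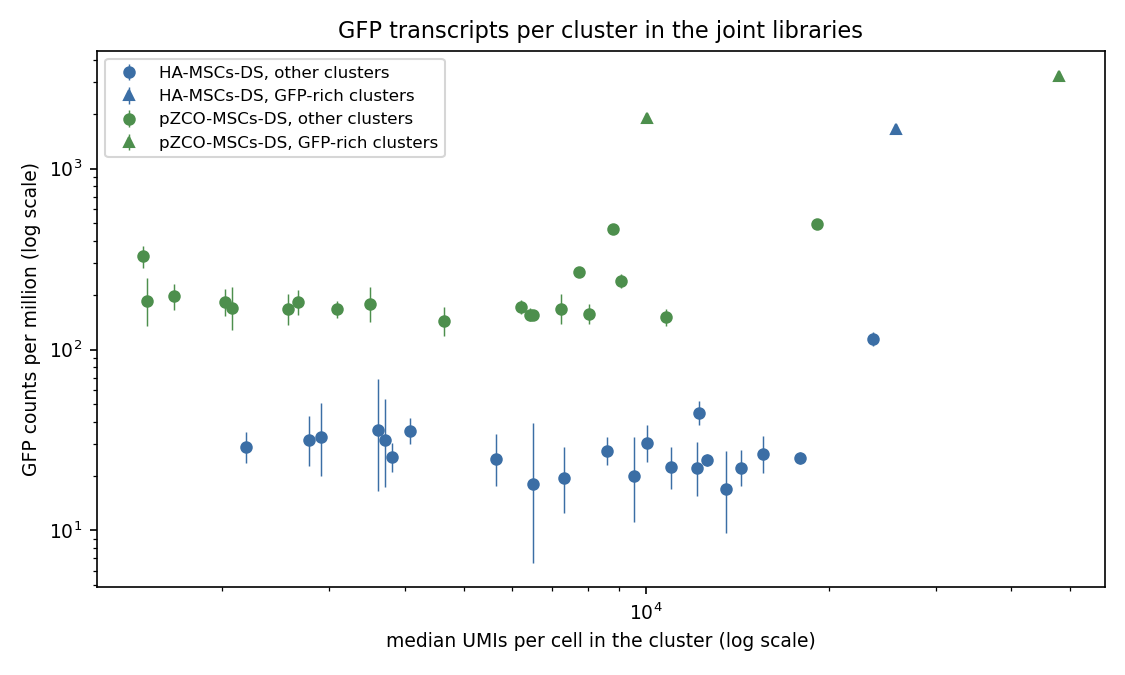
GFP CPM (log scale) against the median UMIs per cell (log scale) for each cluster of the injected joints with at least 50 cells, with exact 95% Poisson intervals; triangles mark clusters at 5 or more times their library's median cluster. The GFP-rich clusters are cluster 7 (3276 CPM) and cluster 29 (1904 CPM) of pZCO-MSCs-DS and cluster 29 of HA-MSCs-DS at 1661 CPM.

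To ask what the coacervate changed against hyaluronic acid as a carrier, the pZCO-MSCs-DS joint library was compared with the HA-MSCs-DS one over all kept cells. Cartilage genes stood higher with the coacervate: type II collagen (Col2a1) at 631 against 129 CPM, 4.80 to 4.98 times higher, aggrecan (Acan) at 271 against 73.2 CPM and the lubricin gene Prg4 at 3313 against 1191 CPM. The chondrocyte transcription factor gene Sox9 stood at 124 against 21.1 CPM and Cytl1 at 306 against 29.1 CPM. Inflammatory and macrophage genes stood lower, with the B cell-attracting chemokine gene Cxcl13 at 35.2 against 2078 CPM, 57.0 to 61.3 times lower, the Fc receptor gene Fcgr3a at 17.1 against 963 CPM and Ccl4 at 281 against 4744 CPM. Il1b stood at 518 against 2632 CPM, Tnf at 84.8 against 332 CPM and Il6 at 82.5 against 276 CPM. Among the genes furthest apart were the interleukin-33 receptor gene Il1rl1 (821 against 69.5 CPM), Fam25a (306 against 1.64 CPM), the imprinted RNA H19 (61.4 against 2.33 CPM) and Penk (467 against 33.8 CPM). The make-up of the libraries moved with the genes of this comparison: 14 of 14 measured chondrocyte markers were higher and 16 of 17 macrophage markers lower, as the shares of these cells were. Il1rl1, Fam25a and Penk were leading genes of GFP-rich cluster 7, which had 901 pZCO-MSCs-DS and 0 HA-MSCs-DS cells. Stromal-like cells gave 57.1% of the pZCO-MSCs-DS counts against 18.7% of the HA-MSCs-DS counts.

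Of the cartilage matrix list all 22 measured members were higher in the pZCO-MSCs-DS tissue (median 1.79 [1.75, 1.81], percentile 100). Hypertrophy and mineralization had 9 of 13 higher, 2 lower (median 1.98, percentile 100), with type X collagen (Col10a1) at 155 against 20.7 CPM. Of the pro-inflammatory mediators 0 of 30 were higher and 24 lower (median -1.85 [-1.87, -1.83], percentile 0). Of the interferon response 1 of 32 were higher and 30 lower (median -2.09 [-2.16, -2.01], percentile 0). Of class II 0 of 9 were higher and 9 lower (median -3.40 [-3.42, -3.39], percentile 0), with Cd74 at 1438 against 15221 CPM. Efferocytosis and lipid handling (3 of 24 higher, 16 lower, median -0.83), eicosanoid synthesis (6 of 10 lower, median -1.42) with Ptgs2 (151 against 692 CPM), and the IL-4 response (3 of 30 higher, 14 lower, median -0.43) with Arg1 (13.4 against 619 CPM) were lower. The IL-4 response median turned to 0.13 with means over cells, and it was higher in macrophage-like cells alone. Protease inhibitors (10 of 15 higher, 3 lower, median 1.05) with the collagen chaperone gene Serpinh1 (1069 against 253 CPM), and fibrillar matrix (12 of 27 higher, 4 lower, median 0.53) with the collagen cross-linking gene Lox (32.0 against 4.78 CPM) were higher. Trophic factors (12 of 23 higher, 3 lower, median 0.63) and the cell cycle (16 of 31 higher, median 0.61) were higher too, and mesenchymal surface genes leaned higher (8 of 17 higher, 3 lower, median 0.40), while the glucocorticoid response was split (6 of 13 higher, 5 lower, median 0.50). Matrix-degrading enzymes were split (7 of 22 higher, 6 lower, median 0.24 [0.17, 0.28], percentile 42.8). Mmp3 stood at 878 against 563 CPM and Mmp13 at 24.4 against 10.3 CPM, Adamts5 at 16.1 against 12.1 CPM, and the macrophage cathepsin gene Ctss at 173 against 1183 CPM. Scaling matters in this pair: trimmed-mean (TMM) scaling moved log2 ratios by -0.42 and turned the enzyme median to -0.16, while it left the cartilage median at 1.37. It brought fibrillar matrix to 0.10, trophic factors to 0.24, the cell cycle to 0.19, mesenchymal surface genes to 0.03 and the glucocorticoid response to 0.08. The median over all measured genes was 0.31 before and -0.10 after it. Glycolysis (2 of 18 higher, 5 lower, median -0.11), apoptosis (4 of 18 lower, median -0.24), endoplasmic reticulum stress (3 of 17 higher, 3 lower, median -0.16) and oxidative stress (4 of 17 higher, 4 lower, median 0.18) were mixed. The respiratory chain (3 of 29 higher, 1 lower, median 0.19), hypoxia (4 of 15 higher, 2 lower, median 0.32), metal response (1 of 5 higher, median 0.37) and immediate early genes (3 of 17 higher, 2 lower, median 0.20) leaned slightly higher, but with TMM scaling these 4 turned to -0.23, -0.07, -0.01 and -0.23, and oxidative stress to -0.25.

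Within chondrocyte-like cells, clusters 9 and 18 in both tissue libraries (100 cells of HA-MSCs-DS and 245 of pZCO-MSCs-DS), the cartilage matrix list itself was nearly level (4 of 27 higher, 3 lower, median 0.01 [-0.07, 0.07]). Col2a1 stood at 6876 against 5817 CPM, Acan at 1564 against 1476 CPM, and Prg4 at 9017 against 17797 CPM. Hypertrophy genes were higher (9 of 15 higher, 1 lower, median 1.0), with the growth plate signal gene Ihh at 168 against 22.4 CPM, Bglap at 139.5 against 22.9 CPM and Col10a1 at 2725 against 1335 CPM. Ihh, Panx3, Pth1r and Bglap were detected as markers in cluster 18 and not in cluster 9. Cluster 18 held only 32 of the 100 HA-MSCs-DS cells and 101 of the 245 pZCO-MSCs-DS cells. The make-up of the class thus differed too, and whether these genes differed within cluster 18 was not tested. With cells thinned to 1500 UMIs (7 and 3 left out of pZCO-MSCs-DS and HA-MSCs-DS), Col10a1 was found in only 15.1% and 6.19% in that order, against 2.23% and 0.146% of GFP-rich stromal-like cells. Before thinning it was in 33.9% and 11%, against 42.7% and 4.31%. Fibrillar matrix was higher (11 of 25 higher, 1 lower, median 0.56), but Col1a1 (1971 against 536 CPM) did not stand above free RNA there and rose in B cell-like cells, where it was not above free RNA either (1209 against 519 CPM). Matrix-degrading enzymes were lower (2 of 21 higher, 8 lower, median -0.50) with Mmp3 at 1388 against 3178 CPM and Adamts1 at 13.2 against 76.8 CPM. Pro-inflammatory mediators were lower as well (24 of 27 lower, median -1.67) with the siderophore-binding gene Lcn2 at 274 against 1538 CPM. Free RNA from other cells bears on the latter: over the 14 mediators that stood above the level free RNA would give, the median was -0.86. For the interferon response (20 of 23 lower, median -2.08) it was -0.77 over 7, and of the class II genes (8 of 8 lower, median -3.92) only 1 stood above it.

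In GFP-rich stromal-like cells, cluster 7 with part of cluster 29 in the pZCO-MSCs-DS tissue against cluster 29 in the HA-MSCs-DS tissue, fibrous matrix and inflammation genes were lower with the coacervate. Fibrillar and fibrous matrix had 3 of 27 higher, 23 lower (median -1.32 [-1.38, -1.21]), with Postn at 3.17 against 139 CPM, the fibronectin gene Fn1 at 2612 against 8504 CPM and Mfap5 at 5.26 against 106 CPM. Matrix-degrading enzymes had 1 of 21 higher, 14 lower (median -0.81), with the gelatinase gene Mmp2 at 64.4 against 601 CPM. The interferon response had 27 of 28 lower (median -2.79, and -2.93 over the 20 above free RNA), with Cxcl10 at 50.6 against 1202 CPM and the guanylate-binding gene Gbp1 at 0.775 against 51.7 CPM. Pro-inflammatory mediators had 27 of 27 lower (median -2.04, and -1.69 over 11), with Lcn2 at 26.8 against 472 CPM, and class II 9 of 9 lower (median -3.66, with 1 above free RNA). Trophic factors were lower (3 of 20 higher, 13 lower, median -1.19), with Tnfaip6 at 51.2 against 325 CPM and the chemokine gene Cxcl12 at 14.6 against 92.2 CPM. The cartilage matrix list had 16 of 21 higher, 2 lower (median 1.36), but the median over the 7 above free RNA was only 0.42. Even of these, Col2a1 stood at 278 against 44.3 CPM, close to its level in B cell-like cells (286 against 41.2 CPM), while Sox9 stood at 117 against 39.3 CPM. The cell cycle was higher (17 of 31 higher, median 0.69), as were Fam25a (557 against 4.92 CPM), H19 (91.8 against 3.74 CPM) and the inhibitor gene Timp4 (85.6 against 4.0 CPM). Each library's cells of this class come almost wholly from a cluster of their own. The classes also differed in GFP per cell. The limit of 5 or more GFP UMIs at 1000 CPM or more was passed by 280 of 720 HA-MSCs-DS cells and 727 of 955 pZCO-MSCs-DS cells. What the other cells are was not tested. With cells chosen by that limit, 0 of the 8 reported list medians turned and 2 moved.

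Macrophage-like cells came mostly from clusters 28, 19 and 4 in the HA-MSCs-DS tissue and clusters 20 and 4 in the pZCO-MSCs-DS tissue, and differed in kind between them. With the coacervate, Arg1 stood at 95.3 against 1054 CPM, Fcgr3a at 129.7 against 1606 CPM, and Cxcl13 at 294 against 3574 CPM. Nos2 stood at 1364 against 6101 CPM and Ccl4 at 2434 against 7814 CPM, while Il1b was at 3286 against 3944 CPM and Tnf at 652 against 528 CPM. Tnf turned to a log2 ratio of -0.28 with TMM scaling within the class, and it was found in 26.4% against 35.9% of cells thinned to 1500 UMIs (115 and 121 shallower cells left out), against 2.99% and 7.11% of B cell-like cells. The bone-resorbing protease gene Ctsk stood at 92.6 against 4.96 CPM, the elastase gene Mmp12 at 107 against 12.0 CPM, the lipase gene Lpl at 36.8 against 1.11 CPM and Igf1 at 172 against 39.1 CPM. The interferon response (28 of 31 lower, median -1.32) and class II (8 of 9 lower, median -1.38) were lower. The cell cycle (26 of 30 higher, median 1.45) and the IL-4 response (21 of 33 higher, 3 lower, median 0.77) were higher. Pro-inflammatory mediators leaned lower (3 of 30 higher, 13 lower, median -0.48). TMM scaling within the class moved log2 ratios by -0.59 and brought that median to -1.07 and the IL-4 response median to 0.18. In synovial lining fibroblast-like cells of the tissue, fibrillar matrix (2 of 27 higher, 19 lower, median -1.04), interferon (1 of 29 higher, 25 lower, median -1.83) and pro-inflammatory genes (4 of 29 higher, 19 lower, median -1.30) were lower. Ifit1 stood at 4.22 against 211 CPM, Il6 at 335 against 953 CPM and Prg4 at 34739 against 18967 CPM. Their matrix-degrading enzymes were mixed (4 of 25 higher, 7 lower, median -0.19), with Mmp3 at 6235 against 6094 CPM. In neutrophil-like cells, mostly clusters 11, 13, 17 and 12 against 12 and 13, pro-inflammatory (23 of 30 lower, median -1.23) and interferon genes (1 of 28 higher, 19 lower, median -1.39) were lower, with Ccl4 at 94.5 against 2394 CPM. There the interferon median was -0.58 over the 18 members above free RNA. The HA-MSCs-DS class also held cluster 30 (157 cells), with 14 macrophage markers detected and Ccl4 among its leading genes. It gave 2721137 of the 11073744 HA-MSCs-DS counts of the class and was not left out.

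**Figure D4:**
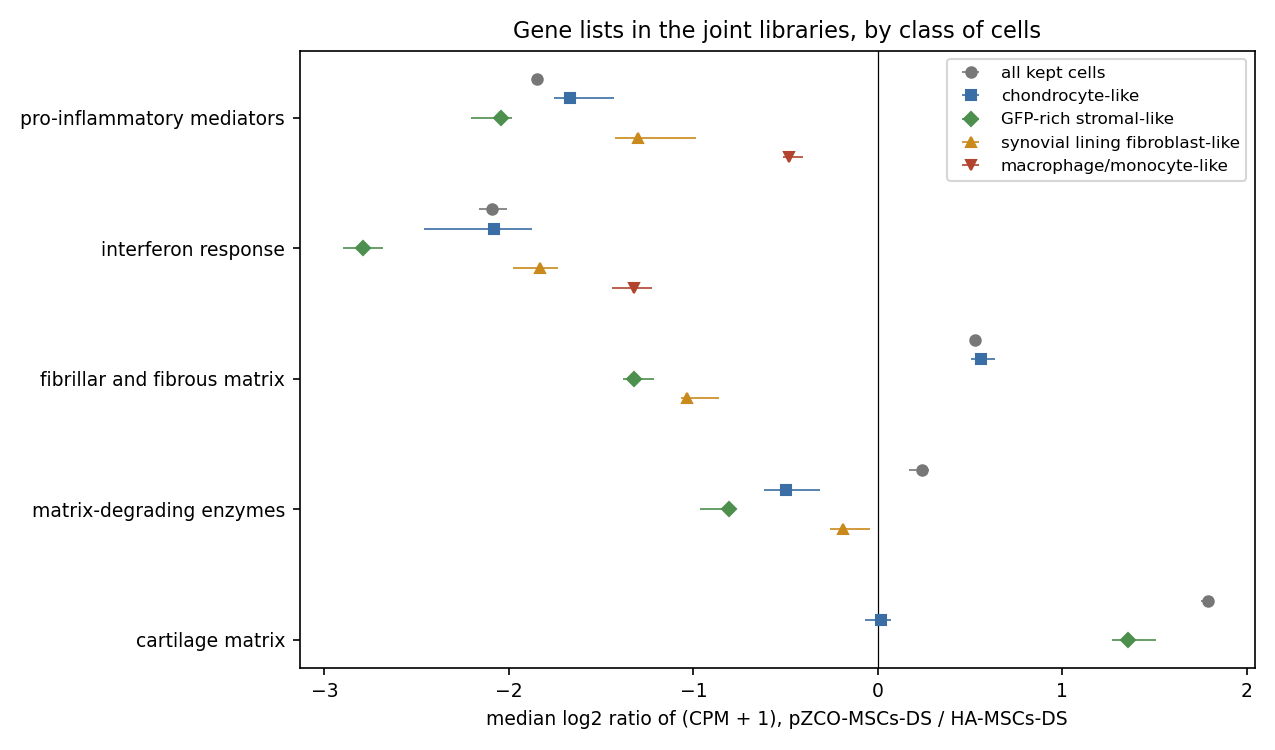
Median log2 ratio of (CPM + 1), pZCO-MSCs-DS over HA-MSCs-DS, for 5 gene lists in all kept cells and in 4 classes of cells of the joint tissue; bars are 95% intervals of counting error, and medians are drawn for the lists reported for each class. The cartilage matrix median is 1.79 over all cells and 0.01 in chondrocyte-like cells.

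To see how the injected joints stood against the Control tissue, HA-MSCs-DS was first compared with it. Macrophage genes were far higher: Cxcl13 at 2078 against 2.12 CPM, Fcgr3a at 963 against 1.5 CPM and the complement gene C1qa at 3074 against 56.5 CPM, 52.6 to 56.2 times higher. Ccl4 stood at 4744 against 105 CPM and the lipid carrier gene Apoe at 11345 against 737 CPM, with 16 of 17 macrophage markers higher. Cartilage genes were lower, with Col2a1 at 129 against 1610.4 CPM, 12.3 to 12.7 times lower, Sox9 at 21.1 against 308 CPM, Acan at 73.2 against 326 CPM and Col10a1 at 20.7 against 484 CPM. The osteocalcin gene Bglap at 0.480 against 169.8 CPM and the haemoglobin gene Hbb at 78.4 against 9044 CPM were lower too. All 10 erythroid, 10 B cell and 15 chondrocyte markers were lower. Class II had 9 of 9 higher (median 3.11 [3.04, 3.19]), and the interferon response 27 of 33 higher, 3 lower (median 1.77). Pro-inflammatory mediators had 28 of 30 higher, 1 lower (median 1.68), with Il1b at 2632 against 919.9 CPM, Tnf at 332 against 31.6 CPM and Il6 at 276 against 86.4 CPM. Efferocytosis (17 of 24 higher, 2 lower, median 1.82) and glycolysis genes (10 of 18 higher, median 0.69) were higher. Cartilage matrix had 25 of 25 lower (median -3.34 [-3.37, -3.30]), and hypertrophy 2 of 13 higher, 11 lower (median -2.89). Trophic factors had 5 of 26 higher, 16 lower (median -1.79), the cell cycle 30 of 31 lower (median -1.29) and protease inhibitors 3 of 14 higher, 7 lower (median -0.97). The IL-4 response (12 of 32 higher, 10 lower, median 0.17) was mixed although Arg1 stood at 619 against 18.4 CPM. Matrix-degrading enzymes (9 of 24 higher, 7 lower, median 0.30) and fibrillar matrix (6 of 26 higher, 9 lower, median -0.15) were mixed. TMM scaling moved log2 ratios of this pair by 0.70, which turned the fibrillar median to 0.55 and brought the median of all genes from -0.52 to 0.14. How the Control cells were chosen is not in the labels, so injection and sort are not separated in this pair.

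The pZCO-MSCs-DS tissue was then set against Control in the same way. Over all kept cells the inflammatory lists were split: pro-inflammatory mediators had 6 of 30 higher, 6 lower (median -0.07 [-0.09, -0.04]), the interferon response 10 of 25 higher, 10 lower (median -0.10 [-0.13, 0.00]) and class II 2 of 8 higher, 3 lower (median -0.56). The first 2 of these medians changed sign with TMM scaling, which moved log2 ratios by 0.29 and the median of all genes from -0.22 to 0.06. With means over cells they were 0.42 and 0.21. Such medians do not show a return to the Control level, since the make-up of the libraries differed. GFP-rich stromal-like cells gave 43895412 of the 84626803 pZCO-MSCs-DS counts, and Control had 0 of them. Macrophage-like cells made up 18.3% of pZCO-MSCs-DS cells against 5.41% of Control cells. Il1b stood at 518 against 919.9 CPM, Il6 at 82.5 against 86.4 CPM and Tnf at 84.8 against 31.6 CPM. Cartilage genes were below Control (23 of 25 lower, median -1.35 [-1.40, -1.34]), with Col2a1 at 631 against 1610.4 CPM, 2.53 to 2.58 times lower, and Sox9 at 124 against 308 CPM. Acan was at 271 against 326 CPM, a log2 ratio of -0.26 that turned to 0.03 with TMM scaling, and Prg4 at 3313 against 2408 CPM. Hypertrophy genes were lower (8 of 13 lower, median -0.87). Among the genes furthest above Control were Gpr15lg (240.3 against 0.826 CPM), Il1rl1 (821 against 13.1 CPM) and the detoxifying enzyme genes Gsta1 (269.9 against 3.48 CPM) and Ptgr1 (531 against 12.0 CPM). The quinone reductase gene Nqo1 stood at 874 against 89.1 CPM. These genes, from Gpr15lg to Nqo1, were all among the leading genes of GFP-rich cluster 7. That cluster had 901 pZCO-MSCs-DS and 0 Control cells, so their levels move with its presence. Efferocytosis (13 of 23 higher, 2 lower, median 0.94), glycolysis (10 of 18 higher, 1 lower, median 0.68) and hypoxia (6 of 15 higher, median 0.48) leaned higher. So did oxidative stress (8 of 17 higher, 5 lower, median 0.36) and mesenchymal surface genes (8 of 18 higher, 4 lower, median 0.42) with the antagonist gene Grem1 (116 against 6.20 CPM). The cell cycle (22 of 31 lower, median -0.86) and trophic factors (5 of 27 higher, 12 lower, median -0.38) leaned lower. Fibrillar matrix (9 of 27 higher, 9 lower, median 0.38) and matrix-degrading enzymes (9 of 24 higher, 8 lower, median 0.09) were split, with the protease gene Mmp19 at 93.4 against 11.5 CPM. All 10 erythroid, 10 T cell and 10 B cell markers and 12 of 13 neutrophil markers were lower, which moves with the shares above.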

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

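All tests but that on pro-inflammatory members above free RNA were chosen only after the result had been seen. That test, too, rests on a free-RNA limit and a split by class that were set after the data had been seen.

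GFP, a transcript outside the gene comparisons, stood at 288 CPM [285, 291] in the HA-MSCs-DS joint and 1801 CPM [1792, 1810.0] in the pZCO-MSCs-DS joint, against 0 counts in Control, at most 0.0575 CPM. GFP is missing from Control's gene list, so its count of 0 does not show whether it was looked for. It appeared in every class with 50 or more cells of both injected joints, while clusters with at least 0.5 times the GFP of the richest one held 15.2% of pZCO-MSCs-DS and 6.80% of HA-MSCs-DS cells, which argues against most sorted cells making GFP transcripts at a level like it. In classes other than stromal, lining and chondrocyte-like cells, GFP lay at 19.5 to 30.4 CPM (HA-MSCs-DS) and 143 to 327 CPM (pZCO-MSCs-DS), a median of 0.576 and 0.605 times the level predicted from free RNA, so free RNA may account for it there. A lower level of their own transcripts, cells that carry GFP protein with little transcript, and a permissive sort, were not tested and stay open.

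Stromal-like cells were found in all 3 macrophage cultures, at 8.04% of IFNg-LPS, 34.8% of IL-4 and 40.1% of pZCO-MSCs-DS cells. The labels name added cells for pZCO-MSCs-DS alone, so the lowest share elsewhere, 8.04%, argues against the cells of the coacervate system as the only source. Per cell, macrophage marker counts in stromal-like cells were a median of 0.459 (IFNg-LPS), 0.257 (IL-4) and 0.222 (pZCO-MSCs-DS) times those in macrophage-like cells. A macrophage with stromal free RNA, or a doublet, would hold 1 time or more, so these are argued against as the whole source, but doublets may make up a part, above all with IFNg-LPS. Stromal cells of the source of the cultures, or of a shared co-culture, may explain them and were not tested, and what part of those in the pZCO-MSCs-DS culture was added stays open.

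Pro-inflammatory and class II genes were lower in the chondrocyte-like and GFP-rich stromal-like cells of the pZCO-MSCs-DS joint than of the HA-MSCs-DS joint, whose library was rich in macrophage-like cells. Over the pro-inflammatory members above free RNA the median log2 ratio was -0.86 [-0.95, -0.79] over 14 members in the first class and -1.69 [-1.77, -1.62] over 11 in the second. These members were still lower with the coacervate. A member could pass in either library, so one high in the HA-MSCs-DS cells could enter through the difference itself. Some transcripts, such as Col2a1, also lie above the estimate in several classes. The test therefore cannot decide whether free RNA was the whole cause. The median over all measured genes was -0.0176 in the first class and 0.0580 in the second. Scaling to CPM removes any difference that lowers all genes alike, so these values cannot speak to that. They argue only against a shift of the typical gene, as from a few genes taking most of the counts. For class II genes, free RNA from the macrophages of the HA-MSCs-DS joint may be the cause, since only 1 gene stood above free RNA in each class. The design names the carrier as the difference between these joints, a biological explanation that single libraries cannot test.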

How the results depend on the processing

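Settings within classes, clusters 18 and 21, clusters 0 and 26, other naming rules, GFP-rich cells by GFP UMIs, and all settings of the lists not named in the plan were chosen only after the result was seen; the others were planned. No paired analysis was possible because each group has 1 library. Named genes over all cells kept their sign without a cell filter (380 of 498 within the counting interval, 118 outside) and without doublets (179 of 323, 144 outside), and with TMM scaling 13 of 498 turned and 375 moved. Of the lists not named in the plan, 15 of 132 turned with TMM scaling, 16 with means over cells and 0 without a filter or with the smaller pseudocount. Within classes, TMM scaling turned 1 of 77 reported list medians and 1 of 81 named genes, free RNA 1 of 77 medians, and the choice by GFP UMIs 0 of 8. Counting cluster 0 as stromal-like turned 2 and moved 8 of 12 medians and moved 5 of 5 genes, with none turned. Leaving cluster 26 out of macrophage-like cells turned 1 and moved 6 of 22 medians, and turned 1 and moved 9 of 15 genes. Checks of class-level medians were also counted per median and setting, over TMM scaling, free RNA and doublets left out. For medians not reported, 108 checks turned, 699 moved and 1513 stayed, against 2, 76 and 136 checks of those reported. The settings of clusters 0 and 26 and of GFP UMIs are not in these counts. The reported set was chosen after those counts were seen. The macrophage-like shares were the same under both other naming rules. Doublets could not be left out for IL-4 over IFNg-LPS, where none were called. For shares, each cell filter and the doublet setting also meant new clusters and names. No IFNg-LPS or IL-4 cell was a called doublet, so with doublets left out their shares moved through the new clusters alone. Values that turned or moved follow as log2 medians, or log2 ratios of the genes named, with the cause not tested. Changes near 1.5-fold lie at the limit set for calls and are mostly missed, and 1 library per group limits everything else.

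With TMM scaling over the summed counts, IL-4 over IFNg-LPS moved for pro-inflammatory (-3.26) and IL-4 response (0.68). pZCO-MSCs-DS over IFNg-LPS moved for pro-inflammatory (-1.79). IL-4 over IFNg-LPS turned sign for class II (-0.019), protease inhibitors (-0.059), Anxa1 (-0.043) and Col1a1 (-0.065). pZCO-MSCs-DS over HA-MSCs-DS moved for cartilage matrix (1.37). pZCO-MSCs-DS over HA-MSCs-DS turned sign for matrix-degrading enzymes (-0.16), respiratory chain (-0.23), oxidative stress (-0.25), metal (-0.0096), hypoxia (-0.068), immediate early (-0.23), H2az1 (-0.28), Calr (-0.087), Ier3 (-0.060), Tnfaip6 (-0.12) and Adamts5 (-0.012). HA-MSCs-DS over Control turned sign for oxidative stress (0.63), metal (0.25), immediate early (0.46), fibrillar matrix (0.55), mesenchymal surface (0.59), Ldha (0.37), Mmp3 (0.52) and Col1a1 (0.55). pZCO-MSCs-DS over Control turned sign for pro-inflammatory (0.22), interferon (0.19), apoptosis (0.026), Ccl2 (0.14), Acan (0.030) and Il6 (0.22). With TMM scaling within classes, pZCO-MSCs-DS over IFNg-LPS turned sign for class II in macrophage-like cells (-0.0054). pZCO-MSCs-DS over HA-MSCs-DS turned sign for Tnf in macrophage-like cells (-0.28). With every list member of 1 count or more, IL-4 over IFNg-LPS moved for pro-inflammatory (-3.01). pZCO-MSCs-DS over IFNg-LPS moved for pro-inflammatory (-1.44). IL-4 over IFNg-LPS turned sign for glucocorticoid (0.0056), hypertrophy (0.017) and protease inhibitors (-0.0043). pZCO-MSCs-DS over IFNg-LPS turned sign for metal (-0.11), matrix-degrading enzymes (-0.049) and trophic factors (-0.0071). pZCO-MSCs-DS over IL-4 turned sign for IL-4 response (0.0044) and mesenchymal surface (-0.040). pZCO-MSCs-DS over HA-MSCs-DS moved for cartilage matrix (1.67) and matrix-degrading enzymes (0.38). HA-MSCs-DS over Control turned sign for metal (0.037) and hypoxia (-0.055). pZCO-MSCs-DS over Control turned sign for eicosanoids (-0.079) and protease inhibitors (-0.022). With means over cells of counts per 10000, IL-4 over IFNg-LPS moved for pro-inflammatory (-3.71). pZCO-MSCs-DS over IFNg-LPS moved for pro-inflammatory (-1.88) and IL-4 response (0.30). IL-4 over IFNg-LPS turned sign for class II (-0.13), efferocytosis (-0.073), eicosanoids (-0.093) and trophic factors (0.67). pZCO-MSCs-DS over IFNg-LPS turned sign for glucocorticoid (0.11). pZCO-MSCs-DS over IL-4 turned sign for IL-4 response (0.15) and hypertrophy (0.049). pZCO-MSCs-DS over HA-MSCs-DS moved for cartilage matrix (2.11) and matrix-degrading enzymes (0.62). HA-MSCs-DS over Control turned sign for respiratory chain (-0.0087), oxidative stress (0.22) and immediate early (0.12). pZCO-MSCs-DS over Control turned sign for pro-inflammatory (0.42), interferon (0.21), metal (0.031) and apoptosis (0.070). pZCO-MSCs-DS over HA-MSCs-DS turned sign for IL-4 response (0.13) and oxidative stress (-0.11). With a pseudocount of 0.1 CPM, IL-4 over IFNg-LPS moved for pro-inflammatory (-3.36). pZCO-MSCs-DS over IFNg-LPS moved for IL-4 response (0.68). In macrophage-like clusters only, IL-4 over IFNg-LPS moved for pro-inflammatory (-3.45) and IL-4 response (0.93). pZCO-MSCs-DS over IFNg-LPS moved for pro-inflammatory (-1.64) and IL-4 response (0.30). In macrophage-like clusters with 18 and 21, IL-4 over IFNg-LPS moved for pro-inflammatory (-3.64) and IL-4 response (1.20). pZCO-MSCs-DS over IFNg-LPS moved for pro-inflammatory (-1.64) and IL-4 response (0.30). With list members above free RNA only, pZCO-MSCs-DS over IL-4 turned sign for matrix-degrading enzymes in stromal-like cells (-0.071). With no filter on cells, shares of cells were IFNg-LPS macrophage-like 81.5%, IL-4 macrophage-like 48.5%, pZCO-MSCs-DS macrophage-like 54.8% and HA-MSCs-DS joint macrophage-like 42.0%. With the stricter cell filter, IL-4 over IFNg-LPS moved for IL-4 response (0.82). Shares of cells were IFNg-LPS macrophage-like 78.2%, IL-4 macrophage-like 47.2%, Control joint B cell-like 25.4% and pZCO-MSCs-DS joint stromal-like 23.7%. HA-MSCs-DS over Control turned sign for respiratory chain (-0.0011). pZCO-MSCs-DS over Control turned sign for pro-inflammatory (0.012) and interferon (0.042). With doublets left out, shares of cells were IFNg-LPS macrophage-like 81.5%, IL-4 macrophage-like 59.5%, pZCO-MSCs-DS macrophage-like 58.8% and HA-MSCs-DS joint macrophage-like 45.0%. pZCO-MSCs-DS over HA-MSCs-DS moved for cartilage matrix (1.72). At Leiden resolution 0.5, shares of cells were IFNg-LPS macrophage-like 81.5%, IL-4 macrophage-like 8.39%, HA-MSCs-DS joint macrophage-like 44.6% and pZCO-MSCs-DS joint stromal-like 28.0%. At Leiden resolution 1.5, shares of cells were IFNg-LPS macrophage-like 46.2%, IL-4 macrophage-like 27.7%, pZCO-MSCs-DS macrophage-like 49.4% and HA-MSCs-DS joint macrophage-like 44.4%. With clusters 18 and 21 counted in, the share was IL-4 macrophage-like 62.8%. With cluster 0 counted as stromal-like, IL-4 over IFNg-LPS turned sign for matrix-degrading enzymes in stromal-like cells (0.14). pZCO-MSCs-DS over IFNg-LPS turned sign for matrix-degrading enzymes in stromal-like cells (0.40). With cluster 26 left out of macrophage-like cells, pZCO-MSCs-DS over IFNg-LPS turned sign for class II in macrophage-like cells (-0.00081) and Ccl22 in macrophage-like cells (-1.60). The share was pZCO-MSCs-DS macrophage-like 54.2%.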

Other observations

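Classes outside the accounts above also differed between the injected joints of the tissue set. In stromal-like cells outside the GFP-rich clusters (211 of HA-MSCs-DS and 425 of pZCO-MSCs-DS), the interferon-driven chemokine genes Cxcl11 (12.1 against 351 CPM), Cxcl9 (48.8 against 825 CPM) and Cxcl10 (179.8 against 1094 CPM) stood lower with the coacervate, as did Lcn2 (35.3 against 553 CPM), the fibrous matrix gene Postn (209.9 against 989 CPM), the aggrecan-cutting enzyme gene Adamts5 (109.9 against 222 CPM) and Mmp3 (5243 against 8713 CPM). Higher there were the cartilage gene Comp (5386 against 3081 CPM), the linked growth-related genes Igf2 (84.1 against 10.8 CPM) and H19 (113 against 10.6 CPM) and the matricellular gene Ccn2 (1268 against 426 CPM). In endothelial-like cells (69 and 325), Cxcl11 (59.9 against 572 CPM), Cxcl9 (265 against 829.9 CPM) and Il6 (201 against 781 CPM) were lower, and the stress gene Ddit3 (108 against 34.6 CPM) higher.

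The macrophage cultures also held small groups of other cells. A dendritic cell-like cluster had 155 IFNg-LPS cells of 168, and an osteoclast-like cluster 81 of 83. A natural killer cell-like cluster was found in all 3, with 20 (IFNg-LPS), 11 (IL-4) and 12 (pZCO-MSCs-DS) cells. Over all kept cells of the macrophage cultures, GFP was not among the genes listed in any of the 3 libraries, so it gives no mark of the added cells there. No hypothesis beyond those weighed above was tested.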
